A study of Bos taurus with 30 samples.

How the data were processed

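Skin biopsies of F2 cattle from a cross of Gyr (Bos indicus) and Holstein (Bos taurus) were measured on a bovine expression array (Affymetrix), in which each gene is read by 1 or more sets of short probes. The 30 arrays came from 13 animals, 6 called tick resistant and 7 called tick susceptible in the labels, biopsied before infestation (0 h) and 24 h and 48 h after tick infestation. Total RNA was extracted with Trizol, purified on RNeasy columns, and amplified and biotin labelled from 50 ng with the 3' IVT Express kit, per the labels' protocols.

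The deposited values are log2 signal values made by the authors with MAS5, per the labels. No version is given in the sources used here. Tested on the values, the linear signal had a 2% trimmed mean of 500 in each of the 30 arrays, so they had been scaled to 1 trimmed mean. The array medians differed (7.17 to 7.40 on the log2 scale), which quantile normalized arrays would not. Detection calls are not used here, and the number of arrays limits the precision.

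The deposited log2 values were used without further normalization. Of 24128 probe sets, 112 controls were left out, and 13809 of the remaining 24016 were kept because they lay at or above the median of their array in at least 3 arrays. Gene symbols came from the probe set annotation supplied with the values: 13292 probe sets had 1 symbol, 86 had several and 10638 had none. No genome coordinates are given, because a genome build is not given in the sources used here. For gene lists, each gene was represented by the kept probe set with the highest mean, which gave 7016 genes.

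Arrays were grouped by phenotype and time as the labels give them: 5, 6 and 5 resistant arrays and 3, 6 and 5 susceptible arrays at 0 h, 24 h and 48 h. A linear model of 6 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The 11 comparisons were resistant against susceptible at each time, each pair of times within a phenotype, and the difference between phenotypes of the 24 h and of the 48 h response. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the probe sets kept, with a threshold of 0.05. Each log2 difference is given with its standard error (SE) from the fit.

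Of 38 gene lists written before the data were examined, 36 had at least 5 measured genes and were tested with camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with the correlation estimated for each list. For the comparisons of phenotypes, the mean of a list in each array (its score) was also compared by an exact permutation of the animals. The differences between phenotypes and between times within a phenotype use the same 6 groups, so the comparisons are not independent of each other.

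Genes were named by a rule fixed before the data were examined. It takes the genes past the threshold with the largest changes, the 3 with the smallest p where none passed, the 4 members with the smallest p of each list past the set test, and 2 of each of 4 lists of immune cells. The text gives at most 2 of the 4 for a list, not always the first, and none for some lists; which of them it gives was settled after their values were seen. Other genes are named as chosen after their values were seen.

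The fit was tested on simulated data for the comparison of phenotypes at 48 h, with 200 of 13809 probe sets changed. It recovered 72 of 100 probe sets changed by 1 log2 unit and 95 of 100 changed by 2, with 4 false calls. With no change it called 0, with 659 at an unadjusted p under 0.05. A list of 16 genes shifted by 0.5 was recovered, and 0 of 35 other lists were called. The simulated values were independent between genes and between arrays. They therefore do not show how often the tests call correlated genes, or arrays of the same animals, by chance.

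The alternatives were quantile normalization, centring on the array median, no filter, the animal number as a random block or as a fixed term, only the arrays of the groups compared, no intensity trend, array weights, an added 2-fold threshold, leaving out each array, and the estimated correlation. For the random block the set test was run in its pre-ranked form. Those added after the data were seen were an offset of 16 on the linear signal and 3 animal numbers moved. Terms for XIST as high or low, the 3' to 5' difference of spike-in controls and the mean of 2 epidermal scores were also added then. So were the pre-ranked set test with no block and the estimated correlation with the animal as a fixed term. The antigen presentation list without BOLA and the permutation of list scores were added then too. The same holds for that list without the members that had 80% or more of their variance between animals. The planned change of pseudocount applied to a linear table and was replaced by the offset. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.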

Results

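Genome-wide expression was measured in skin biopsies taken before and after tick infestation, in cattle that differ in resistance to ticks. The 30 arrays came from 6 resistant animals (5 arrays at 0 h, 6 at 24 h and 5 at 48 h) and 7 susceptible animals (3 at 0 h, 6 at 24 h and 5 at 48 h). Array medians lay between 7.17 and 7.40 on the log2 scale, and the number of arrays limits the precision of every value.

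The differences between resistant and susceptible skin that passed a test over all probe sets were at 48 h. Of 36 gene lists, 15 passed the set test at that time with a preset correlation, and 0 with an estimated correlation. CYBA, a subunit of the phagocyte NADPH oxidase, was 1.07 ± 0.18 (SE) log2 units higher in resistant skin, at 10.86 ± 0.17 (SD, n = 5) against 9.80 ± 0.34 (SD, n = 5). The monocyte and macrophage list was higher in resistant skin by a median of 1.16, with 15 of its 16 genes higher. Its members with the smallest p were C1QC (1.67 ± 0.35 SE), which encodes a chain of complement component C1q, and AIF1 (1.10 ± 0.24 SE). No gene of the list passed over all probe sets, and 13 passed when adjusted over the list alone. The list passed the set test at an adjusted p of 5.56e-15 and did not with an estimated correlation (adjusted p = 0.114).

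Complement genes were also higher, by a median of 0.52 over 16 genes, with CFP at 1.28 ± 0.28 (SE) and CFB, complement factor B, 2.82-fold higher. Genes of mast cells, basophils and eosinophils, for short the mast cell list below, were higher by a median of 1.57 over 5 genes. TPSB2, a mast cell tryptase, was at 2.08 ± 0.65 (SE) and FCER1A at 1.57 ± 0.57 (SE). The eicosanoid list was higher by 0.51, led by ALOX5AP (1.44 ± 0.38 SE), which serves leukotriene synthesis, and PTGIS (1.11 ± 0.45 SE). The collagen and extracellular matrix list was higher by 0.52, with MFAP5 at 1.19 ± 0.31 (SE) and FMOD at 1.06 ± 0.32 (SE). Adjusted over the list alone, 3 complement, 2 mast cell, 1 eicosanoid and 3 collagen genes passed, against 0 over all probe sets. These 4 lists had adjusted p of 1.01e-05, 0.00176, 2.88e-04 and 4.25e-06, and 0.213 to 0.283 with an estimated correlation.

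Oxidative burst genes were higher by a median of 0.13, with GPX1 at 0.58 ± 0.13 (SE) beside CYBA, and the matrix protease list by 0.37, with MMP19 at 1.13 ± 0.30 (SE) and TIMP1 at 0.61 ± 0.17 (SE). The antigen presentation list was higher by 0.59, with CD86 at 1.06 ± 0.37 (SE) and BOLA-DRB3 at 0.82 ± 0.33 (SE). BOLA, its member with the smallest p, was read at 5.07 to 7.31 in some susceptible animals, where array medians lay between 7.17 and 7.40. As 98.4% of its variance was between animals, no difference is given. Without BOLA the list was higher by 0.56 (adjusted p = 0.00666, and 0.592 with an estimated correlation). Other members also differed between animals, among them BOLA-DQA2 (95.7% of its variance). Without the members at 80% or more, 11 genes were higher by 0.68 (adjusted p = 7.07e-04, and 0.414 with an estimated correlation). The type 2 list was higher by 0.31, with CCL26 at 1.57 ± 0.56 (SE) and IL33 at -1.38 ± 0.56 (SE). A kept probe set of IL33 had 84.9% of its variance between animals. Hypoxia and glycolysis genes were higher by 0.23, with GAPDH at 0.44 ± 0.12 (SE). Oxidative phosphorylation genes were higher by 0.11. Ribosomal protein genes were higher by a median of 0.05, which turned to -0.02 under quantile normalization. Basal keratinocyte genes were lower by a median of -0.56 (COL17A1 -0.92 ± 0.42 SE; -0.19 and not called without resistant 01), cell cycle genes by -0.24 (MCM7 -0.28 ± 0.11 SE) and sebaceous gland genes by -0.32 (SCD -0.84 ± 0.29 SE). Adjusted p was just under the threshold for the sebaceous list and ran from 8.47e-04 to 0.0363 for the 9 others, and from 0.213 to 0.758 with an estimated correlation. Adjusted over the list alone, 4 matrix protease, 3 type 2, 2 oxidative burst, 2 hypoxia and 1 antigen presentation gene (BOLA) passed, against 1, CYBA, over all probe sets.

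limma called 2 of 13809 probe sets at 48 h, CYBA (adjusted p = 0.0304) and a probe set with no gene symbol that was lower in resistant skin (-0.75 ± 0.13 SE, adjusted p = 0.0323). At an unadjusted p under 0.05 there were 1391, where 690.45 were expected by chance. Neither probe set passed with only the arrays of the groups compared or with array weights. Leaving out 1 array moved the adjusted p of CYBA between 0.0222 and 0.215, and the call was lost without resistant 01, 02, 03 or 05 or susceptible 10. In the exact permutation of list scores, the macrophage, oxidative burst and matrix protease lists reached 0.00794, the smallest p that 5 against 5 animals allow (adjusted p = 0.0952). Of the 15 lists called at 48 h, 4 were lost without resistant 01, and 8 kept the call without each array in turn, the macrophage, mast cell, complement, eicosanoid and collagen lists among them.

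**Figure D1:**
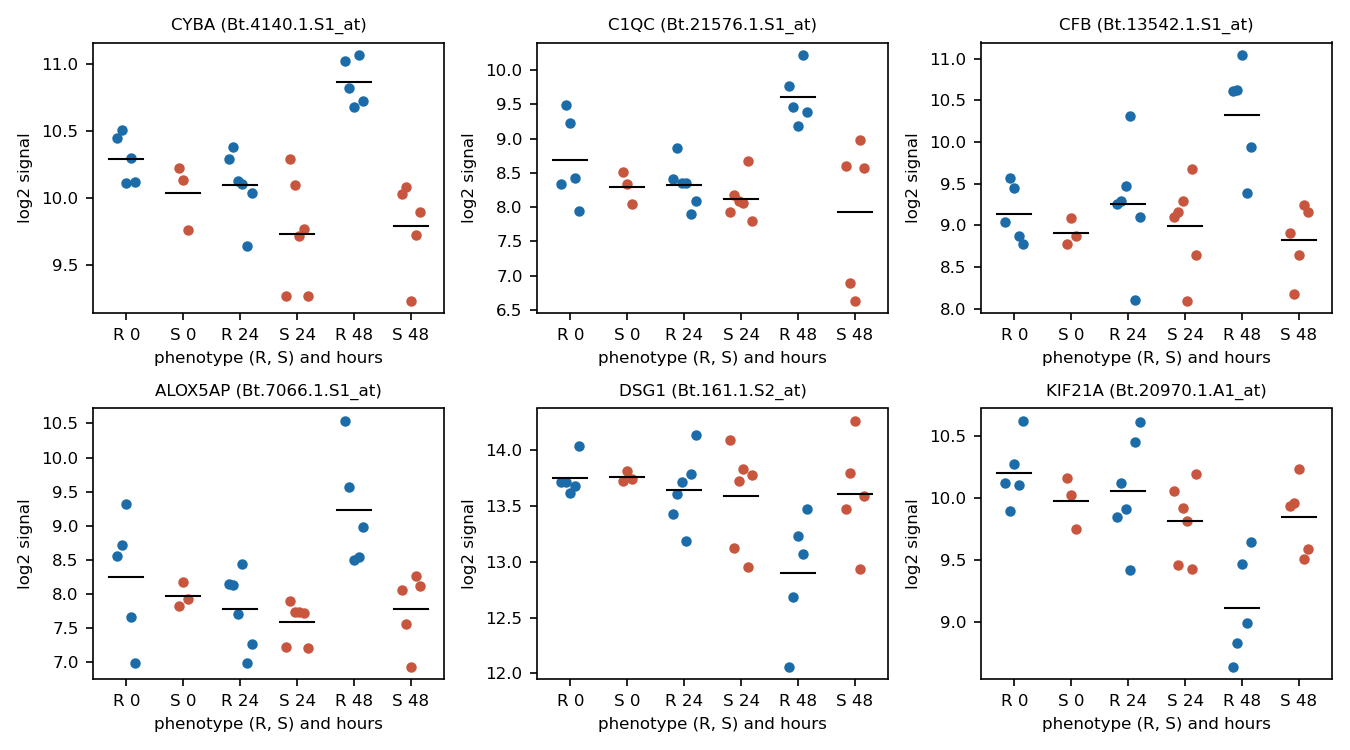
Log2 signal of CYBA, C1QC, CFB, ALOX5AP, DSG1 and KIF21A in each array, with R for resistant (blue) and S for susceptible (red) at 0, 24 and 48 h. Points are arrays and the line is the group mean; CYBA averaged 10.86 in resistant and 9.80 in susceptible skin at 48 h.

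**Figure D2:**
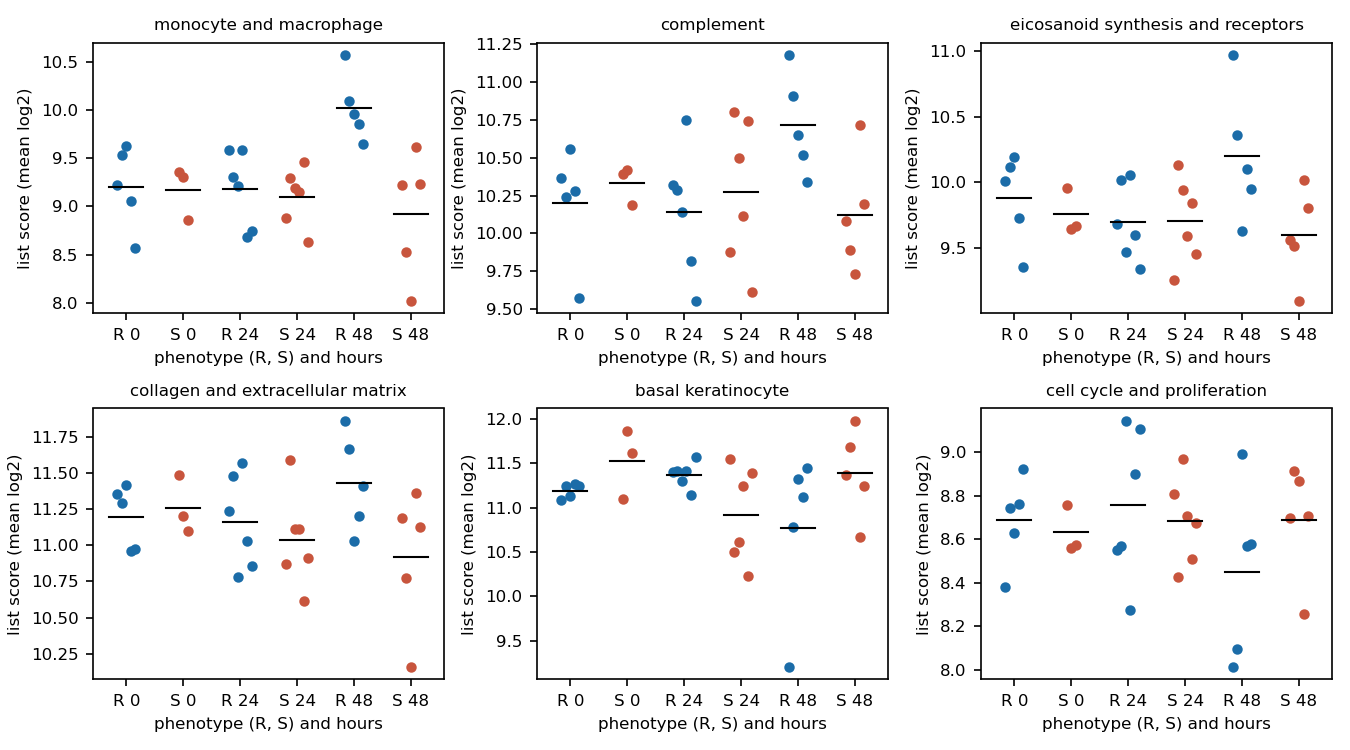
Mean log2 signal of 6 gene lists in each array, by phenotype (R resistant, S susceptible) and hours. Points are arrays and the line is the group mean; the macrophage score averaged 10.03 in resistant and 8.92 in susceptible skin at 48 h.

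Before infestation, interferon-gamma genes were lower in resistant than in susceptible skin by a median of -0.80, in all 7 genes, with GBP5 at -1.47 ± 0.54 (SE) and the chemokine CXCL10 at -1.77 ± 0.65 (SE). Type I interferon genes were lower by -0.42 in all 15 genes, with ISG15 at -1.04 ± 0.46 (SE). T cell and natural killer cell genes were lower by -0.58 (ZAP70 -1.19 ± 0.45 SE), antigen presentation genes by -0.40 (TAP1 -0.73 ± 0.28 SE) and smooth muscle genes by -0.45 (DES -1.58 ± 0.73 SE). Endothelial genes were lower by -0.36 (ENG -0.79 ± 0.27 SE), leukocyte adhesion genes by -0.31 (ANGPT2 -0.84 ± 0.37 SE), sebaceous genes by -0.29 (ACSL1 -0.90 ± 0.40 SE) and basal keratinocyte genes by -0.27 (ITGB4 -0.97 ± 0.27 SE). Ribosomal genes were lower by -0.08, against 0.03 under quantile normalization. These 10 lists had adjusted p of 5.56e-07 to 0.0402, and of 0.387 to 0.724 with an estimated correlation; adjusted over the list alone, 5 interferon-gamma genes and 1 basal keratinocyte gene passed, and 0 over all probe sets. Of the 10 calls, 4 were lost without some single array. In the exact permutation of list scores, 2 of 36 lists had a p under 0.05, and 0 after adjustment. limma called 0 probe sets with 5 against 3 arrays, and 623 had an unadjusted p under 0.05. The genes with the smallest p were COG4 (-0.62 ± 0.17 SE), PIGN (-0.97 ± 0.27 SE) and ITGB4, none past the threshold.

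At 24 h, endothelial genes were lower in resistant skin by a median of -0.45, in 13 of 14 genes, with the angiopoietin receptor TEK at -0.72 ± 0.24 (SE) and PECAM1 at -0.62 ± 0.23 (SE). The leukocyte adhesion list, which also holds PECAM1, was lower by -0.15. Basal keratinocyte genes were higher by 0.36, with KRT15 at 1.09 ± 0.47 (SE) and KRT14 at 0.98 ± 0.46 (SE), and oxidative phosphorylation genes by 0.09, with CYC1 at 0.27 ± 0.14 (SE). The 4 lists had adjusted p of 1.11e-07 to 0.0424, and of 0.817 to 0.888 with an estimated correlation, and no member passed over all probe sets or adjusted over the list alone. Leaving out some single array ended 3 of the 4 calls. In the exact permutation of list scores, 1 of 36 lists had a p under 0.05, and 0 after adjustment. limma called 0 probe sets, with 608 at an unadjusted p under 0.05; DPH3 (-0.58 ± 0.13 SE), SEMA4A (0.68 ± 0.17 SE) and CHD9 (-0.49 ± 0.13 SE) had the smallest p.

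Within resistant animals at 24 h against 0 h, immediate early and heat shock genes were lower by a median of -0.27 (HSPB1 -0.41 ± 0.18 SE, DNAJA1 -0.54 ± 0.26 SE), at an adjusted p of 0.00629, and of 0.975 with an estimated correlation. The call was lost without any 1 of 4 arrays, and with the animal as a fixed term and 3 uncertain animal numbers moved (adjusted p = 0.0766), where interferon-gamma genes passed (0.37, adjusted p = 0.00827, and 0.992 with an estimated correlation). With the numbers as given that list did not pass (adjusted p = 0.0922). limma called 0 probe sets, with 652 at an unadjusted p under 0.05, and KYAT3 (0.48 ± 0.11 SE), HNRNPD (0.47 ± 0.11 SE) and MAGT1 (0.50 ± 0.12 SE) had the smallest p. Without resistant 05 at 0 h it called 2.

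At 48 h against 0 h in resistant animals, macrophage genes were higher by a median of 0.88, in all 16 genes, with AIF1 at 0.88 ± 0.24 (SE) and CD68 at 1.04 ± 0.33 (SE). Antigen presentation genes were higher by 0.59 (B2M 0.34 ± 0.12 SE), complement genes by 0.43 in all 16 (CFB 1.18 ± 0.32 SE), interferon-gamma genes by 0.40 (PSMB8 0.90 ± 0.27 SE) and smooth muscle genes by 0.62 (DES 2.05 ± 0.63 SE). Epidermal differentiation genes were lower by -0.77, with the desmosomal cadherins DSG1 at -0.85 ± 0.24 (SE) and DSC1 at -0.93 ± 0.36 (SE), and keratinocyte wound genes by -0.37 (GJB6 -1.12 ± 0.40 SE). Resistant 01 at 48 h stood apart on the first principal component (65.6, where the next highest array was at 38.3), and without it the epidermal differentiation median was -0.45 and not called (adjusted p = 0.134). Endothelial (0.32), leukocyte adhesion (0.28), eicosanoid (0.32), collagen (0.20) and oxidative phosphorylation (0.09) medians were higher, and immediate early (-0.31) and cell cycle (-0.22) medians lower. The ribosomal median was 0.12, against -0.02 under quantile normalization. The 15 lists had adjusted p of 1.07e-09 to 0.0471, and of 0.493 to 0.666 with an estimated correlation; adjusted over the list alone, 8 macrophage, 4 antigen presentation, 3 complement, 3 epidermal differentiation, 3 smooth muscle and 2 interferon-gamma genes passed, against 0 over all probe sets. Of the 15 calls, 8 were lost without some single array, 6 of them without resistant 01 at 48 h.

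limma called 0 probe sets for that comparison, with 1522 at an unadjusted p under 0.05; COX7A1 (0.96 ± 0.18 SE), KIF21A (-1.09 ± 0.21 SE) and HNRNPAB (-0.50 ± 0.11 SE) had the smallest p. With the animal number as a random block it called 2, COX7A1 (0.98 ± 0.17 SE) and KIF21A (-1.14 ± 0.20 SE), both at an adjusted p of 0.0213. With the animal as a fixed term it called 84, of which 31 were higher and 53 lower, and the oxidative phosphorylation list was not called (adjusted p = 0.234). That fit gained type I interferon (0.45), hair follicle (-0.83), mast cell (0.94) and basal keratinocyte (-0.62) lists, at adjusted p of 5.44e-04 to 0.0282, and of 0.338 to 0.541 with an estimated correlation. With 3 numbers moved it called 108 (62 higher, 46 lower), and the immediate early list was not called either (adjusted p = 0.0588). The 4 lists were gained again, with T cell (0.49), sweat gland (-0.43), matrix protease (0.28) and type 2 (0.29) lists, and the adjusted p of the 8 was 0.264 to 0.559 with an estimated correlation. Among the 45 probe sets called in both, chosen after their values were seen, were LGALS1 (1.02 ± 0.18 SE, and 0.91 with numbers moved) and CFB (1.33 ± 0.29 SE, and 1.23). Over 100 probe sets that differ between animals, the resistant 0 h arrays numbered 03, 04 and 05 were closest to later arrays of animals 04, 05 and 06, so the pairing by number is uncertain for these 3. For 03 and 05, XIST, a proxy for sex, also switched between low and high from the 0 h array to the later arrays of that number.

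At 48 h against 24 h in resistant animals, macrophage genes were higher by a median of 0.92, with C1QC at 1.28 ± 0.33 (SE). Genes of the mast cell, basophil and eosinophil list were higher by 0.99 (ALOX15 1.23 ± 0.69 SE) and complement genes by 0.59 (CFB 1.06 ± 0.31 SE). Antigen presentation (0.46, BOLA-DRB3 0.95 ± 0.32 SE), eicosanoid (0.36, ALOX5AP 1.45 ± 0.36 SE), T cell (0.34, NKG7 0.83 ± 0.38 SE), endothelial (0.37, CLDN5 0.81 ± 0.26 SE) and leukocyte adhesion lists (0.30, ICAM3 0.97 ± 0.31 SE) were higher. So were smooth muscle (0.51), matrix protease (0.34), collagen (0.31) and oxidative phosphorylation (0.06) medians. Basal keratinocyte (-0.65, PERP -0.70 ± 0.19 SE), epidermal differentiation (-0.58, DSG1 -0.74 ± 0.23 SE; -0.22 and not called without resistant 01 at 48 h), sweat gland (-0.36), sebaceous (-0.34), cell cycle (-0.31) and keratinocyte wound (-0.29) lists were lower. The ribosomal median was 0.13, against -0.01 under quantile normalization. The 19 lists had adjusted p of 1.52e-10 to 0.0415, and of 0.377 to 0.637 with an estimated correlation; adjusted over the list alone, 12 macrophage, 4 antigen presentation, 2 complement, 1 eicosanoid, 1 epidermal differentiation and 1 basal keratinocyte gene passed, against 0 over all probe sets. limma called 0 probe sets, with 1332 at an unadjusted p under 0.05; ANP32E (-0.65 ± 0.13 SE), COX7A1 (0.87 ± 0.17 SE) and KIF21A (-0.95 ± 0.20 SE) had the smallest p. Without resistant 01 at 24 h it called 1. Leaving out some single array ended 13 of the 19 list calls, and leaving out resistant 01 at 48 h ended 12. With the animal as a fixed term the oxidative phosphorylation list was not called (adjusted p = 0.198). Type I interferon (0.31), type 2 (0.30) and hair follicle (-0.68) lists were gained, each at an adjusted p of 0.403 with an estimated correlation. With 3 numbers moved, type I interferon and type 2 lists were gained again, with interferon-gamma (0.27) and hypoxia (0.10) lists, at 0.312 to 0.335 with an estimated correlation.

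Within susceptible animals, T cell genes were lower at 24 h than at 0 h by a median of -0.61 (CD3G -1.11 ± 0.46 SE, ZAP70 -1.06 ± 0.44 SE), basal keratinocyte genes by -0.50 (COL17A1 -1.02 ± 0.46 SE) and antigen presentation genes by -0.46 (BOLA-DQA1 -1.33 ± 0.65 SE, with 76.8% of its variance between animals, which are not the same at both times). Interferon-gamma (-0.40, WARS1 -0.40 ± 0.24 SE), smooth muscle (-0.33), hair follicle (-0.29, DLX3 -0.63 ± 0.37 SE), type I interferon (-0.24), collagen (-0.22, ELN -0.68 ± 0.31 SE) and sebaceous (-0.21) medians were lower, and adipocyte genes were higher by 0.32 (LPL 0.87 ± 0.46 SE). With the animal as a fixed term 5 of the 11 calls were lost: interferon-gamma, where the test changed direction (median -0.09), type I interferon (-0.11), collagen (-0.04), hair follicle (-0.35) and smooth muscle (-0.27). The keratinocyte wound list was gained (-0.36, adjusted p = 0.0464, and 0.864 with an estimated correlation). With 3 numbers moved the same 5 were lost, and the sweat gland list was gained in its place (-0.26, adjusted p = 0.0423, and 0.809 with an estimated correlation). Leaving out some single array ended 8 of the 11 calls, and the smooth muscle test changed direction without susceptible 11 at 0 h (median -0.01). The ribosomal median was -0.09, against 0.01 under quantile normalization. The 11 lists had adjusted p of 1.46e-05 to 0.0472, and of 0.571 to 0.706 with an estimated correlation, and no member passed adjusted over the list alone. limma called 0 probe sets, with 318 at an unadjusted p under 0.05; TCOF1 (-0.52 ± 0.13 SE), SEMA4A (-0.76 ± 0.21 SE) and P3H2 (-1.18 ± 0.38 SE) had the smallest p.

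Collagen genes in susceptible animals were lower at 48 h than at 0 h by a median of -0.36, in 24 of 27 genes (ELN -0.64 ± 0.32 SE), and T cell genes by -0.41 in all 12 (CD3G -0.77 ± 0.47 SE). Antigen presentation (-0.38, BOLA-DRA -0.55 ± 0.34 SE), interferon-gamma (-0.35), macrophage (-0.33, C1QA -0.64 ± 0.48 SE), type I interferon (-0.24) and sebaceous (-0.20) medians were lower. The 7 lists had adjusted p of 7.70e-06 to 0.0425, and of 0.658 with an estimated correlation, and no member passed adjusted over the list alone. Leaving out some single array ended 6 of the 7 calls. With the animal as a fixed term 4 were lost: antigen presentation (-0.28), interferon-gamma (-0.11), type I interferon (-0.17) and sebaceous (-0.05). Endothelial (0.20), keratinocyte wound (-0.33), hair follicle (-0.36), smooth muscle (0.24) and immediate early (-0.23) lists were gained, each at an adjusted p of 0.738 with an estimated correlation. With 3 numbers moved the antigen presentation call was kept, the 5 lists were gained again, and so was epidermal differentiation (-0.24), each at 0.654 with an estimated correlation. limma called 0 probe sets, with 131 at an unadjusted p under 0.05; PGP (-0.76 ± 0.23 SE), OSGEP (0.51 ± 0.16 SE) and GPATCH1 (0.74 ± 0.25 SE) had the smallest p.

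Antimicrobial peptide and neutrophil genes in susceptible animals were each lower at 48 h than at 24 h by a median of -0.60. S100A9, which both lists hold, was at -0.92 ± 0.30 (SE). Only 5 of the 28 neutrophil genes written were measured, so that list says little about neutrophils as such. Smooth muscle genes were higher by 0.54 (KCNMB1 0.90 ± 0.40 SE) and basal keratinocyte genes by 0.43 in all 8 (COL17A1 0.82 ± 0.40 SE). Macrophage (-0.18), complement (-0.16, CD55 -0.72 ± 0.38 SE), collagen (-0.13, VCAN -0.74 ± 0.32 SE) and coagulation (-0.10, PLAUR -0.32 ± 0.21 SE) medians were lower and ribosomal genes higher by 0.08. Without susceptible 10 at 48 h the macrophage and collagen medians were 0.04 and 0.06. The 9 lists had adjusted p of 5.27e-07 to 0.0460, and of 0.289 to 0.888 with an estimated correlation; S100A9 passed adjusted over the list alone in both of its lists, and no gene over all probe sets. Of the 9 calls, 8 were lost without some single array. The complement call was lost with the animal as a fixed term (-0.09, adjusted p = 0.217). Matrix protease (-0.30), sebaceous (0.18), immediate early (-0.22) and oxidative phosphorylation (0.07) lists were gained, at adjusted p of 0.453 to 0.905 with an estimated correlation, and the same lists were lost and gained with 3 numbers moved. limma called 0 probe sets, with 259 at an unadjusted p under 0.05; CDH23 (0.47 ± 0.14 SE), PCID2 (0.37 ± 0.11 SE) and PICK1 (0.67 ± 0.21 SE) had the smallest p.

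The difference between the phenotypes in their response is the change in resistant minus the change in susceptible animals, so a positive value can come from a fall in susceptible animals. At 48 h the macrophage response was higher in resistant animals by a median of 1.16, in 15 of 16 genes (CD68 1.39 ± 0.50 SE). The antigen presentation response was higher by 1.15, or 0.95 without BOLA (BOLA-DRA 1.37 ± 0.45 SE), and the mast cell response by 1.12 (TPSB2 2.55 ± 0.99 SE). Interferon-gamma (0.79, PSMB9 1.17 ± 0.40 SE), complement (0.72, CFP 1.35 ± 0.42 SE), T cell (0.62), type I interferon (0.61, IFI6 0.82 ± 0.43 SE) and collagen (0.53, COL6A2 1.25 ± 0.53 SE) medians were higher. So were smooth muscle (0.44), eicosanoid (0.33), leukocyte adhesion (0.30, SELPLG 0.76 ± 0.38 SE), endothelial (0.29, ENG 1.18 ± 0.35 SE), matrix protease (0.28, MMP14 2.17 ± 0.94 SE) and skeletal muscle (0.21, ENO3 0.67 ± 0.30 SE) medians, and the cell cycle median was lower at -0.31 (AURKB -0.53 ± 0.28 SE). The ribosomal median was 0.13, against -0.03 under quantile normalization. The 16 lists had adjusted p of 1.03e-11 to 0.0438, and of 0.276 to 0.507 with an estimated correlation; adjusted over the list alone, 1 interferon-gamma, 1 endothelial and 1 matrix protease gene passed, against 0 over all probe sets. Of the 16 calls, 7 were lost without some single array, 5 of them without resistant 01 at 48 h. The skeletal muscle call was lost with the animal as a fixed term (adjusted p = 0.131), and with 3 numbers moved the smooth muscle call too (adjusted p = 0.101). Oxidative burst (0.14) and epidermal differentiation (-0.57) lists were gained with the numbers as given, at adjusted p of 0.192 and 0.344 with an estimated correlation. Only epidermal differentiation was gained with 3 numbers moved (-0.48, adjusted p = 0.0310, and 0.415 with an estimated correlation). limma called 0 probe sets, with 405 at an unadjusted p under 0.05; COX7A1 (1.03 ± 0.27 SE), SLC35A3 (-1.02 ± 0.29 SE) and RGS10 (1.30 ± 0.37 SE) had the smallest p.

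At 24 h the response of basal keratinocyte genes was higher in resistant animals by a median of 0.68 in all 8 genes (COL17A1 1.37 ± 0.61 SE), of interferon-gamma genes by 0.57 (PSMB9 0.70 ± 0.38 SE) and of smooth muscle genes by 0.49 (DES 1.93 ± 0.93 SE). Antigen presentation (0.41), T cell (0.39, ZAP70 1.31 ± 0.58 SE), sebaceous (0.30, FAR2 4.56 ± 1.73 SE) and type I interferon (0.28, STAT2 0.40 ± 0.19 SE) medians were higher and the adipocyte median was -0.61 (LIPE -0.72 ± 0.31 SE). The ribosomal median was 0.09, and 0.01 under quantile normalization, where its test changed direction. The 9 lists had adjusted p of 6.07e-05 to 0.0498, and of 0.592 to 0.945 with an estimated correlation, and no member passed adjusted over the list alone. Of the 9 calls, 6 were lost without some single array. The T cell (0.13) and interferon-gamma (0.21) calls were lost with the animal as a fixed term. Sweat gland (0.36) and immediate early (-0.22) lists were gained, at adjusted p of 0.864 and 0.877 with an estimated correlation. With 3 numbers moved the T cell call was kept, interferon-gamma was lost (0.43, adjusted p = 0.0762) and 0 lists were gained. limma called 0 probe sets, with 255 at an unadjusted p under 0.05; SEMA4A (0.95 ± 0.28 SE), USP28 (0.92 ± 0.28 SE) and SPICE1 (0.67 ± 0.21 SE) had the smallest p. Across 13809 probe sets, which are not independent replicates, the responses of the 2 phenotypes had a Pearson r of 0.0541 and a Spearman rho of 0.146 at 24 h, and 0.0501 and 0.108 at 48 h. The susceptible responses held 318 and 131 probe sets at an unadjusted p under 0.05, and 351 and 284 with the animal as a fixed term. By chance 690.45 were expected if arrays were independent, which those of 1 animal are not. An r near 0 therefore does not show that the responses were unlike.

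Some lists were not called between phenotypes at 48 h, or at all. In neutrophil genes at 48 h, S100A9 was 0.32 ± 0.31 (SE) and S100A8 0.28 ± 0.41 (SE) in resistant against susceptible skin. The list median was 0.28 (adjusted p = 0.365, and 0.658 with an estimated correlation), over the 5 of 28 written genes that were measured. Melanocyte genes came closest at 24 h against 0 h in susceptible animals (median 0.62, adjusted p = 0.0615). The animals are not the same at both times, and the pigment genes PMEL and TYRP1 had 95.9% and 94.5% of their variance between animals. The smallest adjusted p of the other lists never called was 0.125 for acute phase proteins, 0.167 for inflammatory cytokines, 0.268 for circadian clock genes and 0.298 for the glucocorticoid response. Too few genes were measured to test B cells and plasma cells (4 genes, median 0.21 in resistant against susceptible skin at 48 h) or erythrocytes and platelets (2 genes, median 0.44).

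**Figure D3:**
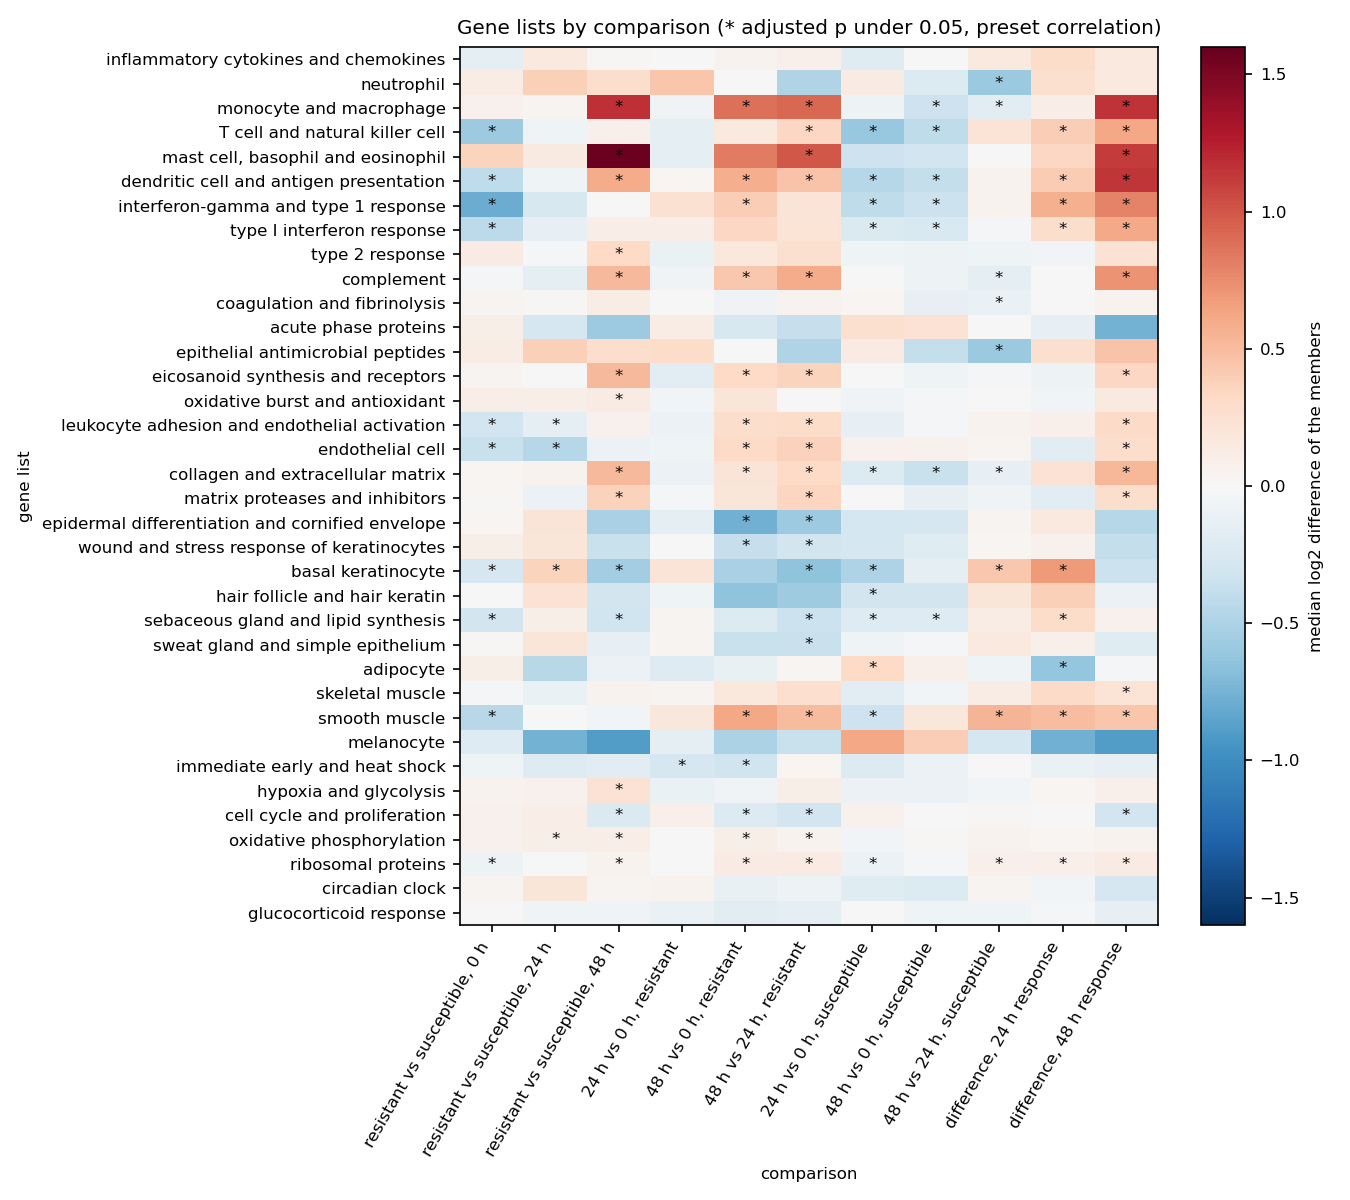
Median log2 difference of the members of 36 gene lists (rows) in 11 comparisons (columns), from blue (lower) to red (higher), with a star where the adjusted p with a preset correlation was under 0.05. The macrophage list was 1.16 higher in resistant than in susceptible skin at 48 h; no starred list passed with an estimated correlation, and ribosomal list tests changed direction under quantile normalization in 7 comparisons.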

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

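The 10 array flags and the 25 differences between responses below follow fixed rules. The tests that weigh the macrophage pattern, and all counts of splits, were chosen or read after the result was seen. A count of splits that reach a result includes the real grouping. Where 100 splits are given, they were drawn from 462 (phenotypes, 24 h), 126 (phenotypes, 48 h) or 112 (difference of responses) possible ones.

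With a preset correlation, the test of a difference between the phenotypes in their response passed for some gene lists of immune cells and skin structure. At 48 h the response in resistant minus susceptible animals had a median log2 difference of 1.16 for macrophage, 1.15 for antigen presentation (0.95 without BOLA) and 1.12 for mast cell genes. The median was 0.79 for interferon-gamma, 0.72 for complement, 0.62 for T cell, 0.61 for type I interferon, 0.53 for collagen and 0.44 for smooth muscle genes. It was 0.33 for eicosanoid, 0.30 for leukocyte adhesion, 0.29 for endothelial, 0.28 for matrix protease, 0.21 for skeletal muscle and -0.31 for cell cycle genes, and 0.13 for ribosomal genes (-0.03 under quantile normalization). At 24 h it was 0.68 for basal keratinocyte, 0.57 for interferon-gamma, 0.49 for smooth muscle, 0.41 for antigen presentation, 0.39 for T cell, 0.30 for sebaceous, 0.28 for type I interferon, -0.61 for adipocyte and 0.0865 for ribosomal genes, the last with a test that changed direction under quantile normalization. Each was marked because the test of the difference passed with a preset correlation, and none passed with an estimated one. A difference of responses also holds the gap at 0 h, where there were 3 susceptible arrays. The interferon-gamma score was 7.83 in resistant and 8.84 in susceptible skin at 0 h, and 8.32 and 8.44 at 48 h. The macrophage score was 9.20 and 9.17 at 0 h, and 10.03 and 8.92 at 48 h.

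In 10 of 190 groups of values, 1 array lay far from the others of its group, and chance gives about 1 in 20. The gap to the nearest array divided by the range was, in susceptible animals at 48 h, 0.810 for mast cell genes (animal 10, lowest) and, for animal 11, 0.793 for antigen presentation, 0.720 for leukocyte adhesion and 0.922 for smooth muscle genes (highest), and 0.824 for keratinocyte wound and 0.855 for sweat gland genes (lowest). It was 0.819 for smooth muscle genes in resistant 05 at 48 h (lowest), 0.752 for hair follicle genes in resistant 05 at 0 h, 0.645 for hypoxia genes in resistant 04 at 24 h and 0.634 for clock genes in susceptible 10 at 24 h (highest). Animal 11 gave 5 of the 10, and without its 48 h array the comparison of phenotypes at 48 h called 14 probe sets in place of 2.

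Macrophage genes such as C1QC and AIF1, none of them past the threshold over all probe sets, were higher in resistant than in susceptible skin at 48 h. The list passed with a preset correlation and not with an estimated one (adjusted p = 0.114). Of 3 explanations weighed, the values argue against sex and the labelling reaction as the whole cause, and cannot decide on less epidermis. Less epidermis in the resistant biopsies would raise the genes of other cells alike. The macrophage score minus the mean of 9 scores of other cells was 0.76 higher (exact permutation p = 0.00794). The macrophage list was picked for its difference in these same arrays, which favours a small p here, so this p cannot decide. By exact permutation the macrophage score was not apart from the mast cell (p = 0.683), antigen presentation (p = 0.0794) or neutrophil score (p = 0.333) alone. Resistant 05 and susceptible 11 stood apart in smooth muscle genes. Without them the value was 0.81 (exact permutation p = 0.0286, the smallest that 70 splits allow). Smooth muscle (exact permutation p = 0.0571) and skeletal muscle (exact permutation p = 0.0857) were then not apart either. All of the 9 scores but neutrophil (0.32 to 0.02) then differed more between phenotypes, smooth muscle going from 0.01 to 0.56. Less epidermis stays open, as a part or the whole of the cause. At 48 h XIST, a proxy for sex, was high in 4 of 5 resistant and 2 of 5 susceptible arrays. With XIST as high or low as a term the macrophage median was 1.16. With the spike-in difference, a measure of the labelling reaction, it was 1.24. With the mean of 2 epidermal scores it fell to 0.81, so part of the difference moves with the epidermal score. An effect of RNA quality was not tested. The 3' minus 5' difference of GAPDH averaged 0.60 ± 0.25 (SD, n = 5) in resistant and 0.78 ± 0.54 (SD, n = 5) in susceptible arrays at 48 h. Chance is not excluded for the number of lists called (28 of 100 splits of the same 10 animals gave as many as 15, highest 23), an influx of macrophages may explain the pattern, as may a change in their expression, and differences between the animals that the design does not name stay open.

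For the comparison of phenotypes at 48 h, 5 of 100 splits called as many as the 2 probe sets (highest of the others 161) and 25 of 100 had as many as 1391 at an unadjusted p under 0.05 (highest 2970), so chance is not excluded. A split that calls 161 may point to a structure of the samples other than phenotype, which was not tested. At 0 h, 8 of 56 splits reached 623 probe sets (highest 920) and 9 of 56 reached 10 lists (highest 15). At 24 h, 41 of 100 reached 608 (highest 2130) and 86 of 100 reached 4 lists (highest 20). Chance is not excluded in any of these.

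For the times within resistant animals, splits exchanged times within the animal numbers given. At 24 h against 0 h, 7 of 32 reached 652 probe sets (highest 994) and 31 of 32 reached 1 list (highest 21). Between 24 h and 48 h, 2 of 32 reached 1332 (highest 1633) and 5 of 32 reached 19 lists (highest 21), and chance is not excluded. The 16 splits at 48 h against 0 h are too few for a share under 0.05: 3 reached 1522 (highest 1621), 5 reached 15 lists (highest 20), and with the animal as a fixed term 2 reached 84 calls (highest 119). With 3 numbers moved, 1 of 16, the real one, reached 108 (highest 0).

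For susceptible animals, the 8 splits at 24 h and at 48 h against 0 h are too few for a share under 0.05. At 24 h, 7 reached 318 (highest 600) and 3 reached 11 lists (highest 15). At 48 h, 8 reached 131 (highest 1098) and 4 reached 7 lists (highest 15). Between 24 h and 48 h, 39 of 48 reached 259 (highest 3151, which may again point to such a structure, not tested) and 25 of 48 reached 9 lists (highest 22). For the difference of responses, 66 of 100 reached 255 (highest 851) and 25 of 100 reached 9 lists (highest 19) at 24 h, and 51 of 100 reached 405 (highest 1876) and 14 of 100 reached 16 lists (highest 20) at 48 h. Chance is not excluded in these.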

How the results depend on the processing

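The settings that move 3 animal numbers, add an offset, add XIST, the spike-in difference or the epidermal score as a term, use the pre-ranked set test with no block, estimate the correlation with the fixed animal term, leave out BOLA or the antigen presentation members that differ between animals, or permute list scores were chosen after seeing the data.

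The 2 calls at 48 h between phenotypes, CYBA and an unnamed probe set, depended on the setting: 10 probe sets passed when centred on the array median, 4 with no filter, 0 with only the groups compared or with array weights, 1 with an added 2-fold limit, 5 with the block and 3 numbers moved, and 1 with the XIST or the spike-in term. Leaving out 1 array gave 0 to 14 calls: 0 without resistant 01, 02, 03 or 05 or susceptible 10, 1 without susceptible 07 or 09, 9 without resistant 06 and 14 without susceptible 11. CYBA kept its direction in every setting run. The cause was not tested.

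At 48 h against 0 h in resistant animals 0 calls became 2 with the random block, 84 with the fixed term, 4 and 108 with 3 numbers moved, and 2 with the spike-in term, with a range of 0 to 2 on leaving out 1 array (1 without resistant 01 at 0 h, 2 without resistant 06 at 48 h). Of the 84 and the 108, 45 were shared. In resistant animals at 48 h against 24 h, 0 became 5 and 16 with 3 numbers moved and 1 with the spike-in term, with 0 to 1 on leaving out 1 array. At 24 h against 0 h it was 0 to 2. The animal block with the numbers as given changed no other count of probe sets; as a random block, with a pre-ranked form of the set test, it kept 104 of the 116 list calls and added 3, 107 in all. That form with no block kept all 116 and called 118. As a fixed term it kept 72 of the 87 list calls over time, lost 15 and gained 21 (71, 16 and 25 with 3 numbers moved), and 0 passed with an estimated correlation. The cause was not tested. The other comparisons stayed at 0 in every setting run, leaving out each array included.

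With an estimated correlation, 0 of the 116 list calls passed. The preset test called 91 to 123 on leaving out 1 array and 91 to 118 in the other settings. These totals include calls gained. Of the 116, 31 were lost with no filter and 23 with array weights. Quantile normalization ended 19, and 7 more changed direction. Leaving out some single array ended 71 of the 116, 7 of the 15 between phenotypes at 48 h among them, and 45 were kept without each array in turn. The responses of the phenotypes had a Pearson r of -0.00789 at 24 h and -0.00195 at 48 h with no filter.

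Ribosomal list tests changed direction under quantile normalization, with medians of 0.0251 (0 h), -0.0154 (48 h), -0.0161 and -0.00720 (resistant, 48 h against 0 h and 24 h), 0.00537 (susceptible, 24 h against 0 h), and 0.00893 and -0.0339 (difference at 24 h and 48 h). With the animal as a fixed term, with numbers as given and moved, the interferon-gamma test in susceptible animals at 24 h against 0 h changed direction (median -0.0884) and GBP4 at 48 h against 0 h was 0.12; GNLY in the 24 h difference was -0.0678 with numbers as given. On leaving out 1 array, values ranged from -0.60 to 0.14 for KIT and -0.63 to 0.00906 for S100A12 (phenotypes, 0 h), -0.0575 to 0.70 for S100A8 (phenotypes, 48 h) and -0.58 to 0.14 (resistant, 48 h against 0 h), and -0.58 to -0.0137 for smooth muscle (susceptible, 24 h against 0 h). In susceptible animals at 48 h against 24 h they ranged from -0.38 to 0.0386 for macrophage, -0.26 to 0.0566 for collagen, -0.93 to 0.12 for CSF1R and -0.80 to 0.32 for TPSB2, the highest values without animal 10. The cause was not tested. The number of arrays limits what these settings can tell apart.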

Other observations

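All tests in this part were chosen after the values were seen, and so were the genes named.

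Some pigment and histocompatibility genes, chosen for it, had a high share of variance between animals, a share that includes the difference between phenotypes. In 23 arrays of 9 animals, differences between animals made up 95.9% of the variance of PMEL, 94.5% of TYRP1, 93.3% of TYR, 95.3% of MC1R and 96.8% of BOLA-DQA5, against a median of 46.6% over all probe sets and 34.3% with shuffled animals. PMEL, a melanosome protein, was 6.43 in resistant 06 at 24 h and at 48 h, and 12.96 and 13.21 in resistant 05. HSPA1A was read between 3.42 and 5.55 in the 3 arrays of animal 10 by a probe set that gave 12.02 to 14.79 in the 27 others, and between 4.67 and 5.61 by a second that gave 11.43 to 14.59. The 3 other probe sets of the gene kept were within the range of the others in animal 10 (12.64 to 14.27, 9.88 to 10.30 and 8.90 to 9.16).

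At 0 h, the resistant arrays numbered 03, 04 and 05 resembled later arrays of other animals. Over 100 probe sets chosen on 24 h and 48 h arrays of other animals, 3 of 3 were closest to the next number: the array numbered 03 to animal 04 (mean r 0.930, against -0.488 with its own number), 04 to 05 (0.878 against 0.486) and 05 to 06 (0.902 against -0.547). PMEL was 5.82 in the 0 h array numbered 05 and XIST was -0.41 in that numbered 03, against 12.10 and 12.11 in 03 later. Of the other 0 h arrays, 5 of 5 were closest to their own number. Later arrays of those animals were used to choose the probe sets, which favours that result. That result therefore cannot decide whether expression changed between biopsies. For the arrays numbered 03 and 05, the XIST values argue against it, since the sex of an animal does not change. For 04, XIST cannot tell. Numbers shifted by 1 at 0 h may explain the 3 matches to the next number. Such a shift leaves group comparisons untouched and bears on those that pair animals.

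The BOLA probe set was low, between 5.07 and 7.31, in 4 of 7 susceptible animals and between 10.96 and 13.39 in the other susceptible and all 6 resistant animals (Fisher's exact test, two-sided, p = 0.0699). A response to infestation is argued against, since 4 of 4 susceptible animals with 2 or more arrays stayed on 1 side at all times, and 2 of 3 were low at 0 h. A donor variant under the probes with the transcript present cannot be told apart from an absent or silent allele, because 0 other probe sets of the gene were kept. An inherited difference in this gene may account for the low readings, and whether it relates to resistance stays open.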
